A study of Mus musculus with 16 samples.

How the data were processed

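The labels describe 24 mice of both sexes carrying the S100a5-tauGFP reporter, kept for 40 h in chambers with an air flow of 3.1 L per min. From 26 h on, octanoic acid or clean air as the vehicle was given for 10 s every 20 min. Olfactory mucosa of 3 mice was pooled, dissociated and sorted into GFP+ and GFP- cells, and 50 to 100 ng of RNA from each of the 16 samples was hybridized to a Clariom S array. The deposited values are log2 signals, 1 per probe set and array, made by the authors with Affymetrix Expression Console; its version, the summary method and the background step were not stated, and the log2 scale was read from the values, which run from 2.13 to 19.5 with close medians across arrays. No raw intensities were used.

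The table holds 28846 probe sets, of which 6640 are controls. Of the other 22206, 19572 carry 1 gene symbol and 2634 have no name and were left out. Where a gene had more than 1 probe set the brightest over all arrays was kept, which left out 67 and gave 19505 genes. All had an Entrez identifier in the reference gene table for GRCm38.p6, used for names only; gene positions were not in it, so none are given. Olfactory receptors (1091) were found by symbol. Class I or II was to be read from the newer Or names, which the table lacks, so it was taken from the older MOR family number (1 to 42 class I, 100 and above class II) for 1067 receptors and from neighboring genes for 24, giving 122 class I and 969 class II receptors.

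The background is the median of 5222 negative-control probe sets, 6.20 log2 over all arrays and 5.80 to 6.77 on single arrays. The 95th percentile of these controls was 10.4 log2, so a signal above the median is not proof of expression. Where the mean of the dimmer group lay under the background or above it by less than its SD, arrays under it were raised to it and the fold is called a lower bound; no fold is given where both groups lay there. The limit of 1 SD was set after the values were seen, and it lowers the fold of Retnlg with octanoic acid from 923 to 718. Other folds come from the values as deposited. For list medians "floored at the background", group means under the background, and not single arrays, were raised to it for every gene of the list.

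Comparisons were chosen before the data were examined. The within-pool difference, log2 GFP+ minus log2 GFP-, was formed for each of the 8 pools, since the mouse numbers show that both sorted samples of a pool come from the same mice. limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) tested the difference between the treatments, which is the odor effect on GFP enrichment, and the mean of each treatment against 0, with 4 pools per treatment. The GFP+ and the GFP- arrays were also compared between treatments, 4 against 4. P values were adjusted by Benjamini-Hochberg over all genes at 0.05, and again over the list alone for each list.

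The labels also give odor and vehicle pools the same numbers. Correlations of their deviations from the group means were 0.179, 0.110, 0.237 and 0.100 for the within-pool differences, 0.371, 0.100, 0.219 and 0.138 in GFP+ cells and 0.408, 0.100, -0.0986 and 0.153 in GFP- cells, which barely reaches the limit of 0.1 set for a pairing in the differences and in GFP+ cells and does not in GFP- cells. A replicate block on that number, paired odor against vehicle, changed no call. The smallest adjusted p with it was 0.781 for the odor effect, 0.104 for receptors adjusted over the list alone, 0.826 in GFP+ cells and 0.915 in GFP- cells.

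Genes were named by a fixed rule, leaving out Gm and Rik gene models: the 10 largest rises and the 10 largest falls past the threshold in each enrichment, the 5 smallest p where no gene passed, S100a5, and members of the lists with or without a call. 31 gene lists were fixed before the data were examined, 26 of them by gene name: cell types of the mucosa and the blood, stages of the neuron, activity-dependent and immediate early genes, and pathways. The others are the receptor lists (olfactory, class I, class II, trace amine-associated, vomeronasal). Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over lists, again with a correlation estimated from the data, and with fry. With the estimated correlation 4 of 14 camera calls held with clean air (immediate early, progenitor, microvillous and leukocyte genes), 3 of 12 with octanoic acid (immediate early, progenitor and leukocyte genes), and none in the other comparisons. With 1 pool left out, those for progenitor, microvillous and leukocyte genes held in only 2 to 4 of 8 cases. Those for immediate early genes held in 8 with clean air and 7 with octanoic acid.

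The tests were tried on simulated data, 20 sets with 200 changed genes each and the spreads of these arrays. The simulated genes varied independently, so the shares below do not show the error rate for genes that vary together. For the odor effect 79.1% of 4-fold and 21.4% of 2-fold changes were found and 4.29% of calls were false; for the enrichments 94.8% and 94.9% of 4-fold changes were found and 4.64% and 4.86% of calls were false. Over receptors alone with limma's variance prior from all genes 9.90% of odor-effect calls and 10.2% and 8.37% of enrichment calls were false, above the 5% aimed at; receptors have wider intervals than other genes. With a prior from receptors alone these shares were 3.65%, 4.18% and 4.53%, so counts with that prior, added after this was seen, stand beside the receptor counts. A list of 122 genes shifted by 0.5 log2 was found, and 0 of 29 unshifted lists were called. In that single run, too, the genes varied independently, and the lists were random. It therefore does not show how often camera at the preset correlation calls unshifted lists of correlated genes.

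Alternatives covered other scalings (quantile normalization, and centring each array on its median or on its receptors), no pool block, the pool as a random block, a filter on genes whose highest group mean was below 7.16 log2 (10541 genes and 924 receptors kept), array weights, a trended robust prior, and leaving out each pool. After the data were seen, 3 floors at the background, leaving out 2 pools, the receptor prior, class I tests, the activity-dependent list without S100a5, all lists without single pools and Fisher's exact tests of receptor class were added. The planned test of class I receptors among those that rose with odor was not run, because 0 receptors rose. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.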

Results

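The series measured gene expression in the olfactory mucosa of S100a5-tauGFP mice exposed to octanoic acid, a fatty acid odorant, or to clean air as the vehicle. In these mice a green fluorescent protein is driven by S100a5, a gene that olfactory sensory neurons transcribe in response to their own activity, so that GFP+ cells are enriched for recently active neurons. 24 mice were pooled by 3, and each of the 8 pools was sorted into a GFP+ and a GFP- sample, which gave 16 Clariom S arrays in 4 groups of 4. Arrays have no read depth, and the number of pools limits the precision. The median of the negative-control probe sets, 6.20 log2, serves as the background, and 951 of 1091 olfactory receptor genes had a mean above it. Differences are given as GFP+ minus GFP- of the same pool, in log2 units with the SD over 4 pools, and folds whose dimmer group lay at the background or less than its SD above it are given as lower bounds.

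The enrichment with clean air asks which transcripts the reporter marks without added odorant. GFP+ cells carried more RNA of genes that follow the activity of olfactory sensory neurons. Of the 8 genes on that list 6 were higher in GFP+ cells (7 when adjusted over the list alone) and none was lower. Lrrc3b was higher by 1.90 ± 0.27 log2 (SD, n = 4), Pcp4l1 by 1.86 ± 0.32, Kirrel2, an adhesion molecule of olfactory axons, by 1.15 ± 0.18, and Kcnn2, a calcium-activated potassium channel, by 1.10 ± 0.26. S100a5 itself was higher by 1.32 ± 0.22, and since its reporter set the sorting gate this is no independent finding; without it 5 of 7 were higher (6 adjusted over the list alone). The vesicular glutamate transporter Slc17a6 (0.39 ± 0.12) and Rasgrp4 (-0.23 ± 0.90) did not pass. The list's shift had a camera adjusted p of 2.76e-05, and an adjusted p of 0.106 with an estimated correlation; without S100a5 these were 0.000173 and 0.106.

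Olfactory receptors spread widely around equal signal with clean air. 410 of the 1091 receptors were higher in GFP+ cells and 255 were lower, with 470 and 297 when adjusted over the list alone and 433 and 279 when the variance prior was also taken from receptors alone. The odorant receptor Olfr536 stood 39.5-fold higher in GFP+ cells (14.41 against 9.11 log2), Olfr309 35.5-fold, Olfr211 25.1-fold, Olfr281 21.5-fold and Olfr533 20.7-fold. At least 27.5-fold was found for Olfr481, 26.2-fold for Olfr494, 18.3-fold for Olfr613, 15.1-fold for Olfr981 and 14.97-fold for Olfr372, all with GFP- cells at the background or less than 1 SD above it. At the other end Olfr99 was at least 134-fold lower in GFP+ cells, with a GFP- mean of 13.26 log2. More than 4-fold separated the sorted samples for 178 receptors in favor of GFP+ cells and for 162 in favor of GFP- cells, and more than 16-fold for 12 and 65.

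Leukocyte markers were lower in GFP+ cells of clean-air mice. 11 of 12 fell (12 when adjusted over the list alone), with Ptprc at -5.05 ± 0.61 log2 and Lyz2 at -7.16 ± 1.27 (SD, n = 4). The median of the list was -3.77 log2, or -3.08 with values floored at the background, and its camera adjusted p was 3.21e-17, with 0.0302 as the adjusted p with an estimated correlation. The 10 largest falls among named genes were those of the receptor Olfr99 and of Retnlg (1006-fold), Ngp (949-fold), the siderophore binder Lcn2 (889-fold), the calprotectin subunits S100a9 (at least 623-fold) and S100a8 (at least 493-fold), Chil3 (at least 532-fold), Mmp8 (at least 262-fold), Anxa1 (at least 187-fold) and Ly6c2 (at least 154-fold). Several of these are known from neutrophils, for which no list was tested.

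Immediate early genes, which many cell types transcribe within minutes of a stimulus, were also lower in GFP+ cells with clean air. 15 of 20 fell and none rose (17 fell and 1 rose when adjusted over the list alone). Fos stood at -5.88 ± 0.40 log2, Egr2 at -6.14 ± 0.71, Egr1 at -5.57 ± 0.58 (SD, n = 4) and Btg2 at least 38.5-fold lower, while Jun (-0.67 ± 0.15) and Dusp1 (-0.73 ± 0.17) fell far less. Arc, Npas4 and Egr4 lay at the background in both sorted samples. The list's median was -2.11 log2 (-1.42 floored at the background), and its camera adjusted p of 1.41e-16 was 0.0118 as an adjusted p with an estimated correlation. Leukocyte markers were lower in the same samples, as were the lists of the next paragraph, which does not show that any of them vary together with these genes.

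Markers of younger neurons, dividing cells, and microvillous and tuft cells followed the same direction with clean air. 9 of 15 immature neuron genes fell (10 adjusted over the list alone), with the growth-associated protein Gap43 at -3.15 ± 0.50 log2 (SD, n = 4) and the G protein subunit Gng8 at least 26.7-fold lower. 6 of 7 progenitor genes fell, with Kit at least 12.1-fold lower, and so did 13 of 14 cell cycle genes, with the proliferation marker Mki67 at least 28.7-fold lower. All 10 microvillous and tuft cell genes fell, led by the taste-pathway channel Trpm5, at least 20.6-fold lower. Camera gave adjusted p values of 7.37e-09, 1.27e-05, 6.37e-12 and 6.14e-11 for the 4 lists in that order. The adjusted p with an estimated correlation was 0.106, 0.0302, 0.179 and 0.0302.

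Genes of mature neurons moved little with clean air. 5 of 20 rose (9 adjusted over the list alone) and none fell, with the phosphodiesterases Pde1c (0.78 ± 0.15) and Pde4a (0.73 ± 0.23), the olfactory chloride channel Ano2 (0.50 ± 0.13) and the creatine kinase Ckb (0.88 ± 0.24; SD, n = 4) as examples. The fifth, Slc8a3, lay at the background in both sorted samples. The olfactory marker protein Omp stood at 0.13 ± 0.17 and did not pass. The list's median was 0.26 log2, with a camera adjusted p of 0.00131 and an adjusted p of 0.298 with an estimated correlation.

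limma gave 3006 genes past an adjusted p of 0.05 with clean air, 1138 higher and 1868 lower in GFP+ cells, of which 127 and 280 had both sorted samples at the background. The split into directions depends on the scaling: centring each array on its median gave 6082 higher and 1571 lower, quantile normalization 1813 and 1783, and centring on the receptors 498 and 1856. The median over all genes was 0.11 log2 as deposited, and 0.38, 0.13 and -0.06 under those 3 scalings.

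**Figure D1:**
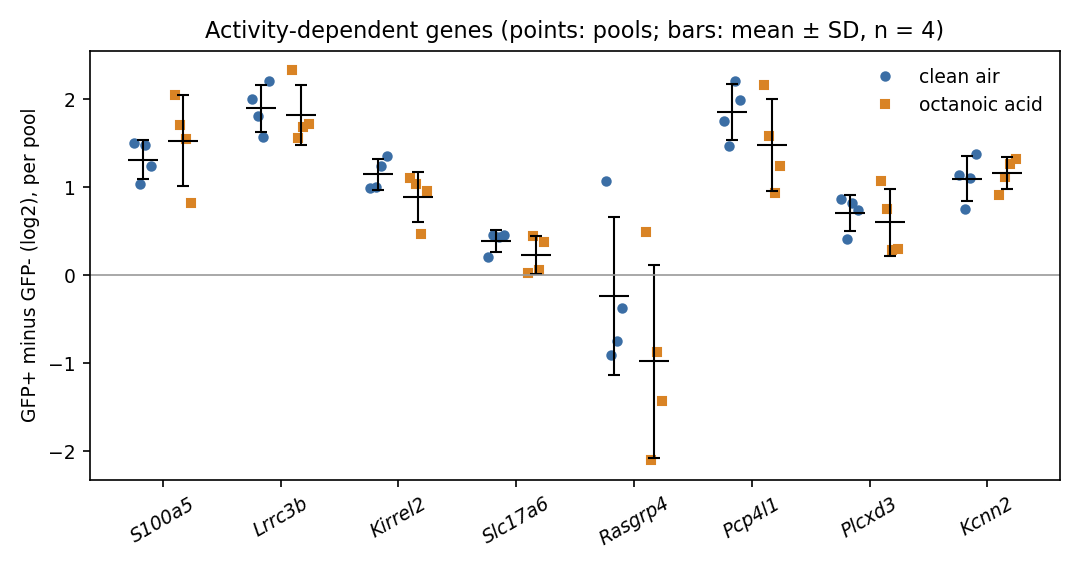
GFP+ minus GFP- difference in log2 units (vertical axis) for the 8 activity-dependent genes (horizontal axis), with a point per pool for clean air (circles) and octanoic acid (squares) and bars for the mean ± SD, n = 4. S100a5, Lrrc3b, Kirrel2, Pcp4l1, Plcxd3 and Kcnn2 lie above 0 in both treatments, with means from 0.60 to 1.90, and Rasgrp4 spreads on both sides of 0.

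The enrichment with octanoic acid asks the same with the odorant present. The same kinds of transcript stood out in GFP+ cells. Activity-dependent genes were again higher, 6 of 8 (6 higher and 1 lower adjusted over the list alone), with Lrrc3b at 1.83 ± 0.34 log2, S100a5 at 1.53 ± 0.52, Pcp4l1 at 1.48 ± 0.52, Kcnn2 at 1.16 ± 0.18 and Kirrel2 at 0.89 ± 0.29 (SD, n = 4). Slc17a6 (0.23 ± 0.21) and Rasgrp4 (-0.98 ± 1.10) did not pass over all genes. The camera adjusted p was 0.000484, and the adjusted p with an estimated correlation was 0.168. Without S100a5 5 of 7 were higher (5 higher and 1 lower adjusted over the list alone), with 0.00319 and 0.173.

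395 of 1091 receptors were higher and 273 lower in GFP+ cells with octanoic acid, with 442 and 309 adjusted over the list alone and 403 and 290 with the receptor variance prior. Olfr536 was 36.6-fold higher, Olfr309 33.6-fold, Olfr110 20.2-fold, Olfr533 20.1-fold, Olfr101 18.8-fold, Olfr281 18.0-fold and Olfr211 17.5-fold. Olfr481 was at least 18.7-fold higher, Olfr494 at least 19.6-fold and Olfr613 at least 14.2-fold. Olfr1297 was at least 338-fold lower, with 15.45 log2 in GFP- cells. The mean over the receptors was -0.06 log2 while their median was 0.27, since the falls were larger than the rises. Class I receptors likewise had a median of 0.12 and a mean of -0.30 (camera direction down, adjusted p 0.316), and class II receptors a median of 0.32 and a mean of -0.03 (camera direction up, adjusted p 0.234).

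Leukocyte markers were again lower in GFP+ cells of odor-exposed mice, where 11 of 12 fell (12 adjusted over the list alone; median -4.19 log2, or -3.63 floored at the background), as did 15 of 20 immediate early genes (median -1.19 log2 floored), with Fos at -6.24 ± 0.78 and Egr1 at -5.89 ± 1.20 (SD, n = 4). The largest falls were those of Ngp (962-fold), Retnlg (at least 718-fold), Lcn2 (815-fold), S100a9 (576-fold), Chil3 (at least 460-fold), S100a8 (480-fold), Mmp8 (at least 387-fold), the receptor Olfr1297, Ly6c2 (at least 210-fold) and Ly6c1 (at least 160-fold). 10 of 15 immature neuron genes (11 adjusted over the list alone), 6 of 7 progenitor genes, 13 of 14 cell cycle genes (14 adjusted over the list alone) and 8 of 10 microvillous genes (9 adjusted over the list alone) fell too. Camera gave adjusted p values of 1.61e-15 for leukocytes, 5.49e-15 for immediate early genes, 8.25e-09 for immature neurons, 3.31e-06 for progenitors, 7.45e-12 for the cell cycle and 1.75e-08 for microvillous cells. In that order the adjusted p with an estimated correlation was 0.0422, 0.0156, 0.147, 0.0326, 0.173 and 0.0583.

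Of the mature neuron genes 4 of 20 rose with octanoic acid (6 adjusted over the list alone), Pde1c by 0.82 ± 0.11 log2, Ckb by 0.56 ± 0.32, Pde4a by 0.53 ± 0.27 and Ano2 by 0.51 ± 0.07 (SD, n = 4). Camera gave an adjusted p of 0.0114, and 0.408 was the adjusted p with an estimated correlation. On the GFP+ array of odor pool 3 the mean of the sustentacular markers was 10.2 log2, higher than on any other GFP+ array, and this array also stood lowest in its correlation with its group.

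limma gave 3347 genes past the threshold with octanoic acid, 1221 higher and 2126 lower, of which 309 and 238 had both sorted samples at the background. Array median centring gave 7791 and 1715, quantile normalization 2587 and 2026, and receptor centring 689 and 1576, with medians over all genes of 0.42, 0.15 and 0.19 log2 against 0.11 as deposited. Leaving out odor pool 3 and vehicle pool 4, chosen after seeing the data, gave 821 and 1814, and 681 and 1551 with clean air.

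The treatments shared most receptor calls. 362 receptors rose in both treatments and 237 fell in both, where 148 and 63.8 would be shared by chance, and none moved in opposite directions. Over all genes 586 rose in both and 1664 fell in both, with 71.2 and 204 by chance and none opposite. Across receptors the enrichments of the treatments had a Pearson r of 0.977 and a Spearman rho of 0.962, and across all genes 0.941 and 0.620. Genes are not independent replicates, so these coefficients carry no p.

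**Figure D2:**
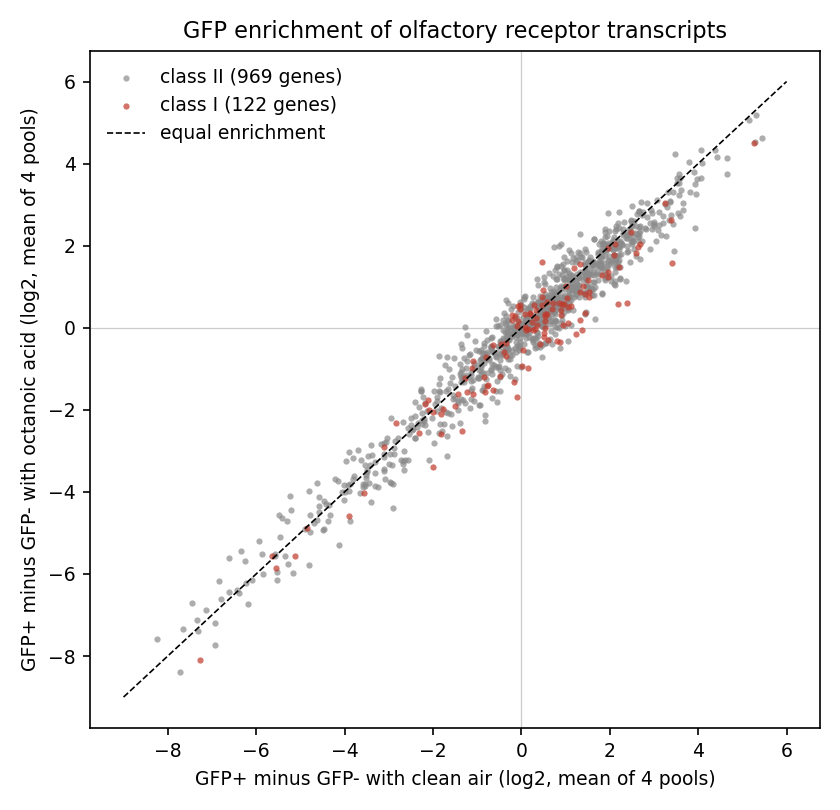
GFP+ minus GFP- difference of 1091 olfactory receptor genes with clean air (horizontal axis) and octanoic acid (vertical axis), in log2 units as means of 4 pools, for 122 class I (red) and 969 class II (grey) receptors; the dashed line marks equal enrichment. The values run from -8.25 to 5.45 with clean air and from -8.40 to 5.19 with octanoic acid, along the dashed line.

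Class I receptors, the family known for carboxylic acid ligands, were less often higher in GFP+ cells than class II receptors with octanoic acid. 25 of 122 class I receptors (20.5%) and 370 of 969 class II receptors (38.2%) were higher, an odds ratio of 0.418 (95% interval 0.253 to 0.668; two-sided Fisher's exact p = 8.81e-05, 0.000352 adjusted over 4 such tests). With clean air the shares were 29.5% and 38.6% (Fisher's exact p = 0.0592, adjusted 0.118). Receptors lower in GFP+ cells made up 26.2% of class I and 24.9% of class II with octanoic acid (Fisher's exact p = 0.740) and 20.5% and 23.7% with clean air (p = 0.496). These tests were added after the data were seen, receptor genes are not independent, and the difference between the treatments was not tested this way. Class I receptors were also dimmer, with a median signal over all arrays of 7.65 log2 against 8.92 for class II receptors. The shares were not matched on signal, so a part played by signal level was not tested.

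The remaining lists showed smaller or mixed changes; where no count adjusted over the list alone is given, it was the same. 4 of 11 Bowman gland genes fell in each treatment: the transcription factor Sox9 (-4.25 ± 0.47 log2 with clean air and -4.40 ± 0.51 with octanoic acid; SD, n = 4), Ltf (at least 127-fold and 189-fold), Lyz1 and Bpifb3. Ltf and Lyz1 are also made by neutrophils or other leukocytes. The median of the Bowman gland list changed sign with the scaling with octanoic acid; the camera adjusted p was 0.000182 and 0.00586, and the adjusted p with an estimated correlation was 0.189 and 0.326. Of 7 guanylyl cyclase D neuron genes 3 fell with clean air (4 adjusted over the list alone) and 4 with octanoic acid, with the phosphodiesterase Pde2a at -3.44 ± 0.55 and -3.52 ± 0.74 (camera adjusted p 0.000423 and 0.00824, and with an estimated correlation an adjusted p of 0.106 and 0.168). Of 11 sustentacular genes Notch2 and Gpx6 fell with clean air and Notch2 with octanoic acid, where the list's median changed sign with the scaling (camera adjusted p 0.00432 and 0.211; with an estimated correlation, an adjusted p of 0.453 and 0.774). The sustentacular median was -0.77 log2 with clean air and -0.27 with octanoic acid, and -0.73 with octanoic acid without odor pool 3 (camera adjusted p 0.000398, and 0.180 with an estimated correlation). The ensheathing glia list had only Apoe falling, at -2.60 ± 1.41 and -2.42 ± 1.64 (2 fell adjusted over the list alone with clean air), and its median of 0.19 had the opposite sign to its mean of -0.36 and its test with clean air.

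Trace amine-associated receptors went both ways: 5 of 15 rose and 4 fell with clean air, and 6 rose and 6 fell with octanoic acid (7 and 5, and 7 and 6, adjusted over the list alone). Taar9 rose by 2.35 ± 0.39 and 2.63 ± 0.74 log2 and Taar4 by 2.36 ± 0.47 and 2.59 ± 1.03, while Taar7a fell, at -1.84 ± 0.46 and -1.72 ± 0.63 (SD, n = 4). The list's median of 0.58 and mean of -0.03 had opposite signs with clean air. 14 of 321 vomeronasal receptors rose with clean air and 24 with octanoic acid (1 and 0 adjusted over the list alone), and their camera adjusted p of 0.00464 and 8.66e-05 became an adjusted p of 0.598 and 0.430 with an estimated correlation. Of 17 axon sorting genes 5 rose and 1 fell with clean air (5 and 2 adjusted over the list alone), and 6 rose and 2 fell with octanoic acid. The protocadherin Pcdh10 rose by 1.76 ± 0.27 and 1.84 ± 0.85, the semaphorin Sema7a by 0.80 ± 0.20 and 0.94 ± 0.19 and the ephrin receptor Epha5 by 0.81 ± 0.32 and 1.16 ± 0.50, while the semaphorin Sema3a fell to -0.90 ± 0.28 and -0.97 ± 0.18. Of 7 transduction shut-off genes 3 rose and 2 fell with clean air, and 3 rose and 1 fell with octanoic acid (4 and 2 adjusted over the list alone); the G protein regulator Rgs2 was at least 7.54-fold and 7.95-fold lower, and the list's median and mean had opposite signs in both treatments.

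Fatty acid oxidation genes fell in 3 of 12 cases with clean air and in 5 with octanoic acid, where 1 rose (2 adjusted over the list alone). The carnitine transferase Cpt1a was 4.15-fold lower with clean air and at least 7.16-fold lower with octanoic acid, and Acadl and the lipid droplet protein Plin2 fell in both treatments; the list's median changed sign with the scaling in both, and its camera adjusted p of 0.0255 with clean air was 0.179 as an adjusted p with an estimated correlation. Of 9 heat shock genes none passed with clean air, and Hspa1a, Hspa1b and Dnajb1 fell with octanoic acid, with Hspa1a at -0.69 ± 0.41 and Dnajb1 at -0.88 ± 0.30; the list's median changed sign with the scaling in both treatments. Of 8 apoptosis genes 1 fell with clean air and 3 with octanoic acid (4 adjusted over the list alone; the median changed sign with the scaling with clean air; camera adjusted p 0.0353 with octanoic acid, and an adjusted p of 0.168 with an estimated correlation). The erythroid enzyme Alas2, the only measured member of its list, fell in both treatments, at -1.50 ± 0.53 and -1.68 ± 0.50. Of 5 ventral-zone genes only Nfia fell, with octanoic acid, and of 5 endothelial genes Pecam1 and Tek, both at the background, did so. None passed among 14 oxidative phosphorylation, 6 respiratory ciliated, 6 fibroblast, 5 horizontal basal and 2 dorsal-zone genes in either treatment. With clean air the median and the camera direction of the endothelial, horizontal basal and dorsal-zone lists had opposite signs.

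**Figure D3:**
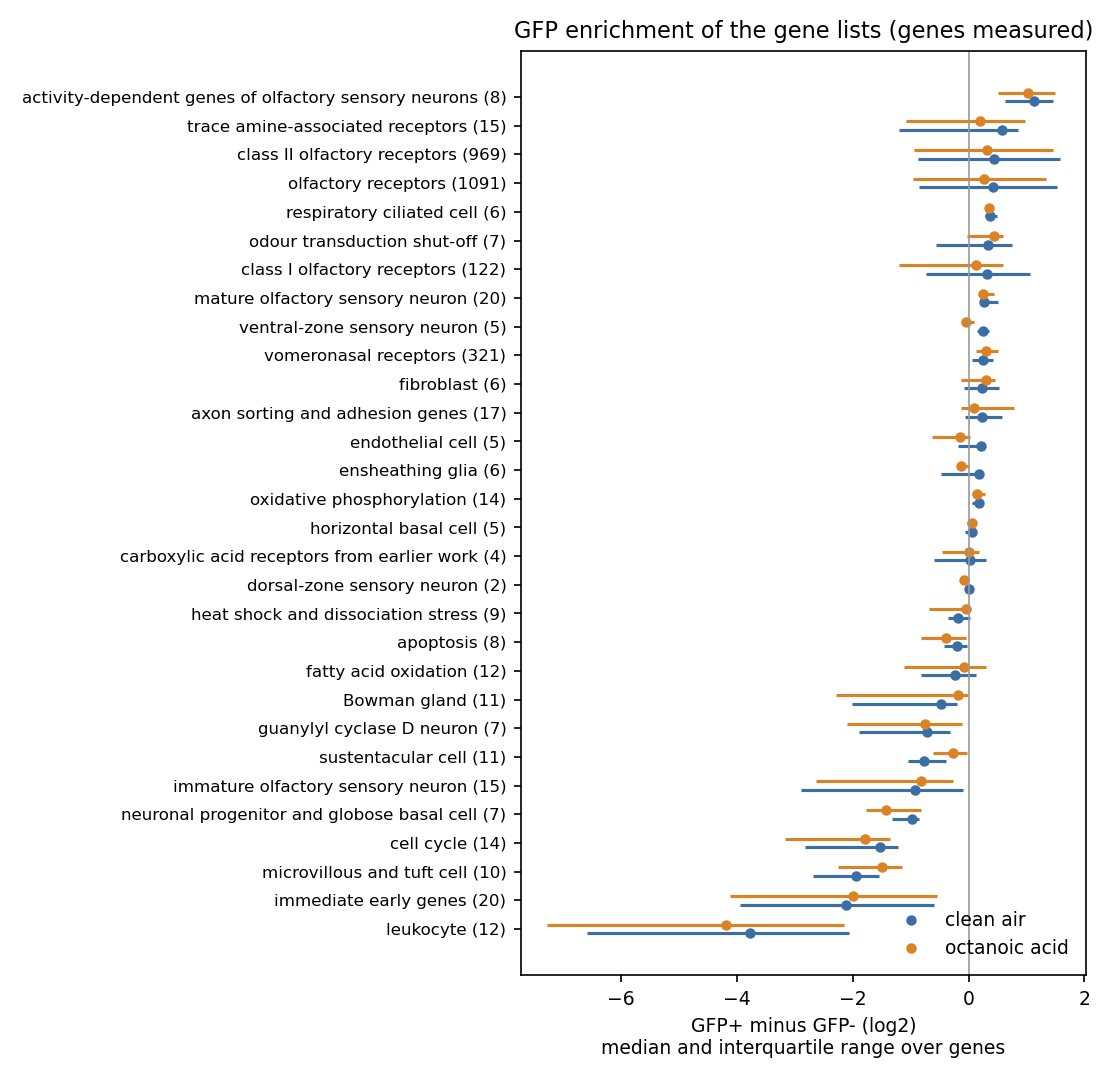
Median (points) and interquartile range (lines) over the genes of each list of the GFP+ minus GFP- difference in log2 units (horizontal axis), by list with its number of measured genes (vertical axis), for clean air (blue) and octanoic acid (orange). Leukocyte genes have the lowest medians, -3.77 and -4.19, and activity-dependent genes the highest, 1.12 and 1.03.

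The effect of octanoic acid on GFP enrichment, the comparison the assay is built for, asks which receptors are more enriched in GFP+ cells with the odorant than without. No receptor and no other gene passed. S100a5 had an odor effect of 0.21 log2 (95% interval -0.39 to 0.82). Among the receptors known from earlier work for carboxylic acids, Olfr690 had 0.34 (-0.93 to 1.61), Olfr691 -0.11 (-0.96 to 0.74) and Olfr544 -0.18 (-0.73 to 0.36); Olfr558 (0.14) lay at the background in all 4 groups, and Olfr78 had no named probe set. Olfr690 fell in GFP+ cells in each treatment, at least 2.71-fold with clean air and 2.69-fold with octanoic acid, and the other 3 did not pass in either. The median of these 4 genes was above 0 and their mean below 0 in each treatment.

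The 5 genes with the smallest p did not pass the correction. They were Micall2 (-1.30 ± 0.26 log2, SE), Ctnna3 (-0.94 ± 0.19), Aadacl4fm4 (1.47 ± 0.31), the stearoyl-CoA desaturase Scd1 (-1.31 ± 0.29) and the class I receptor Olfr243 (-1.42 ± 0.31). Micall2 and Ctnna3 lay below the background in all 4 groups, Aadacl4fm4 in GFP- cells with octanoic acid (5.70 log2) and GFP+ cells with clean air (6.02), and Olfr243 in GFP- cells with clean air (5.76). Scd1 had GFP- means of 9.27 log2 with octanoic acid and 8.02 with clean air, and GFP+ means of 6.08 and 6.14, at the background.

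As a group, class I receptors had lower odor effects than other genes. Their median was -0.32 log2, with 89 of 122 below 0, against -0.11 for class II receptors; the sign of the class II median, but not that of class I, changed with the scaling, and the class I median was -0.07 with arrays centred on the receptors, where the median over all genes was 0.22. The camera adjusted p was 1.59e-05 and the adjusted p with an estimated correlation was 0.938; fry, which compares the receptors with no change and not with other genes, gave an adjusted p of 0.475. Per odor pool the class I median minus the class II median was -0.356, -0.437, 0.134 and -0.519 log2, and per vehicle pool 0.0693, -0.246, 0.0849 and -0.531. The median and the mean or test differed in sign for axon sorting, immature neuron, guanylyl cyclase D, oxidative phosphorylation and fatty acid oxidation genes, none of which passed. No other list passed: sustentacular genes had a median of 0.34, microvillous genes 0.25, cell cycle genes -0.34, activity-dependent genes -0.14 and immediate early genes -0.10, the last 2 with a sign that changed with the scaling. The sign of the sustentacular median rested on odor pool 3 (-0.11 without it) and that of the cell cycle on odor pool 4 (0.07 without it). Adjusted over each list alone, only the fibroblast collagen Col3a1 (-0.82 log2) passed among all lists, and it lay at the background in all 4 groups.

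limma found 0 of 19505 genes past the threshold for the odor effect, with a smallest adjusted p of 0.940 and 871 genes at an unadjusted p under 0.05, where 975.25 would be found by chance. Adjusted over the list alone, 0 of 1091 receptors passed (smallest adjusted p 0.453; 83 at an unadjusted p under 0.05, 54.6 by chance, and 36 with the receptor variance prior). The median half-width of the 95% interval was 0.592 log2 over all genes and 0.853 over receptors. In simulated data with these spreads and independent genes, the test over all genes found 79.1% of 4-fold and 21.4% of 2-fold odor effects. Over receptors alone it found 72.2% and 13.6% with the receptor variance prior. With the prior from all genes it found 78.5% and 30.2%, at 9.90% false calls. At this number of pools 2-fold effects would therefore mostly be missed.

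**Figure D4:**
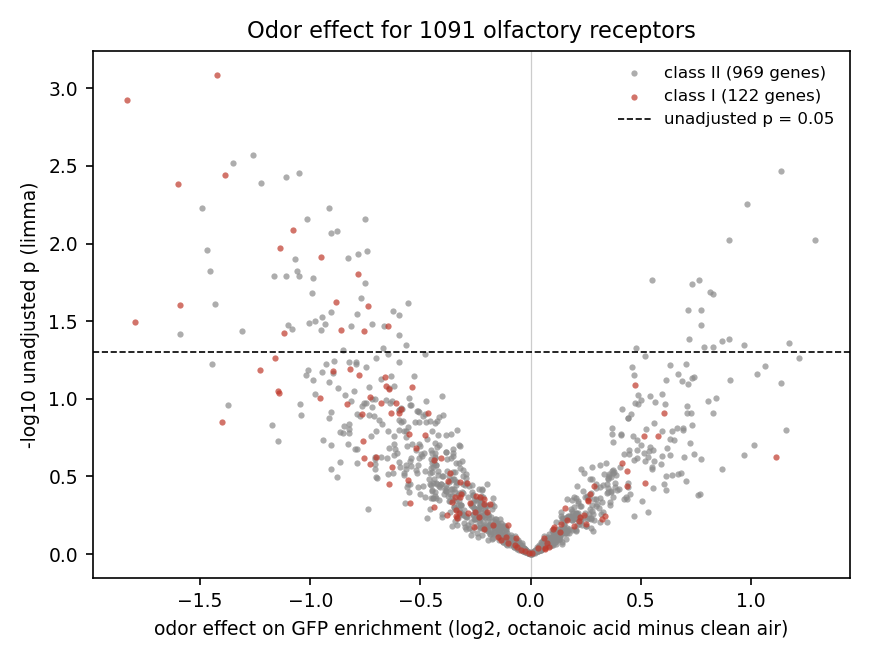
Odor effect on GFP enrichment in log2 units (horizontal axis) against minus log10 of the unadjusted limma p (vertical axis) for 122 class I (red) and 969 class II (grey) receptors; the dashed line marks an unadjusted p of 0.05. 83 receptors lie above the line, none passes the correction over receptors, and 89 of the class I receptors lie left of 0.

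Direct comparison of octanoic acid with clean air in GFP+ cells asks about the marked cells alone. No gene passed. The 5 genes with the smallest p were Lgi2 (0.80 ± 0.16 log2, SE), Sval2 (0.83 ± 0.17), Isx (0.66 ± 0.15), the protease inhibitor Serpinb1a (0.65 ± 0.14) and Krtap21-1 (0.84 ± 0.19). Lgi2, Sval2, Isx and Krtap21-1 lay below the background in both groups, and Serpinb1a stood at 6.75 log2 with clean air. S100a5 differed by 0.15, Lrrc3b by 0.37 and Fos by -0.18. limma gave 0 calls, a smallest adjusted p of 0.955 and 716 genes at an unadjusted p under 0.05; among receptors adjusted over the list alone it gave 0, with 49 unadjusted and a smallest adjusted p of 0.979. The vomeronasal receptors had a median of 0.10 and a camera adjusted p of 0.0101, with an adjusted p of 0.919 with an estimated correlation; they passed in 5 of 8 cases with 1 pool left out, with a median of 0.02 without odor pool 3. The trace amine-associated, endothelial and shut-off lists had a median and a mean or test of opposite sign.

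In GFP- cells the comparison of octanoic acid with clean air covers the cells outside the gate. Again no gene passed over all genes. Adjusted over each list alone Bak1 (0.87 log2) passed among apoptosis genes and Col3a1 (0.54) among fibroblast genes; Col3a1 lay at the background in both groups and Bak1 with clean air. The 5 genes with the smallest p were Esp16 (1.01 ± 0.20 log2, SE), Vmn1r209 (1.23 ± 0.25), the tight junction protein Cldn7 (-0.91 ± 0.19), the transcription factor Hhex (0.73 ± 0.16) and Pgbd1 (-0.69 ± 0.16). Esp16, Vmn1r209 and Pgbd1 lay below the background in both groups, Cldn7 with octanoic acid (6.02 log2) and Hhex with clean air (6.18). Class I receptors had a median of 0.20, cell cycle genes 0.38 and sustentacular genes -0.21, with camera adjusted p values of 2.78e-05, 0.0328 and 0.0261, each with an adjusted p of 0.987 with an estimated correlation. Cell cycle genes had -0.03 without odor pool 4 and passed in 5 of 8 cases with 1 pool left out; sustentacular genes passed in 6, with a median of -0.17 and a mean of -0.04 without vehicle pool 4 (camera adjusted p 0.272). The carboxylic acid receptor, immediate early, mature neuron and heat shock lists had a median and a mean or test of opposite sign. Without odor pool 1 the class I median was 0.13 and its camera adjusted p 0.155; without vehicle pool 1 the median was 0.40, without vehicle pool 4 0.13 and without odor pool 3 0.30. limma gave 0 calls, a smallest adjusted p of 0.985 and 741 genes at an unadjusted p under 0.05; among receptors adjusted over the list alone it gave 0, with 59 unadjusted and a smallest adjusted p of 0.837.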

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

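The tests of dorsal-zone genes, of odor pool 3, of sustentacular markers and of the signal range were chosen after the results were seen. 124 groups of 4 values were searched for a value far from the other 3, where about 6.2 would be found by chance, and 4 were found.

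Class I olfactory receptors had a median odor effect on GFP enrichment of -0.32 log2, listed because camera's test of the difference between treatments passed; with an estimated correlation its adjusted p was 0.938. The difference between class I and class II medians was -0.215, and 8 of the 35 splits of the pools gave one as large (highest other 0.468; 1 of the 8 splits that part all numbered pairs), so chance cannot be excluded. Fewer dorsal-zone neurons among GFP+ cells, where class I receptors are expressed, cannot be told apart from other origins: the median of the 15 trace amine-associated receptors, Nqo1 and Acsm4, dorsal genes too, was 0.118 (95% interval -0.206 to 0.252), but 10 lay above and 7 below 0, and it exceeded the class I median by 0.441, narrowly less than their interquartile range of 0.458. The signal level of the probe sets is argued against by 10000 class II sets of matched level. The middle of their medians was -0.0768 log2 (central 95% -0.165 to 0.0182), no nearer to class I than the -0.107 of all class II receptors. The class I median had percentile 0 among them. These sets were drawn gene by gene, so that percentile takes no account of receptors that vary together. The GFP+ array of odor pool 3 is argued against by the median without that pool, -0.376 (camera adjusted p 3.76e-07, and 0.888 with an estimated correlation). Chance and the dorsal zone stay open, as does an effect of octanoic acid itself, which no further test addressed.

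The GFP+ array of odor pool 3 had a mean correlation with its group of 0.976, where the other 3 had 0.986. Sustentacular cells, the supporting cells of the epithelium, are a candidate source: their 11 markers, none on another list, stood 2.09 log2 above the other 3 arrays in the median, percentile 100 of 10000 gene sets of matched level, and 10 exceeded all 7 other GFP+ arrays. Fibroblast markers stood 0.99 higher (percentile 99.8) and Bowman gland markers 0.371 higher (96.7), while respiratory ciliated markers stood at -0.60. A narrower signal range on that array may also account for part, since the slope of its deviation on mean level was -0.0759 against -0.0148 to 0.0358 on the other GFP+ arrays. The sort should remove cells without the reporter, yet Cyp2g1, a sustentacular cytochrome, averaged 13.33 log2 on the other 3 GFP+ arrays with octanoic acid and 14.61 on the GFP- arrays of these pools, and the shares of the 2 explanations stay open.

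Vehicle pool 4 had a mean GFP+ minus GFP- difference of 0.438 log2 over mature neuron genes, where the other vehicle pools had 0.308 to 0.327. Odor pool 2 had a difference of 5.97 log2 for Olfr481, where the other odor pools had 4.07 to 4.26. Odor pool 1 had a mean difference of 1.27 log2 over the activity-dependent genes, where the other odor pools had 0.665 to 0.763. Of these genes Rasgrp4 set odor pool 1 furthest apart, at 0.49 log2 against -2.10, -0.88 and -1.42 in odor pools 2, 3 and 4.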

How the results depend on the processing

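The 3 floors at the background, leaving out 2 pools, the receptor variance prior, the class I settings, the activity-dependent list without S100a5 and the lists without single pools were chosen after seeing the data. The odor effect gave 0 genes under every setting tried but 1, and so did receptors adjusted over the list alone and both direct comparisons under all of theirs, the replicate block included. The exception was a floor at the common background of all arrays, where 1 gene passed, Zfp874a, named after its value was seen. Its limma adjusted p was 0.0380, against 0.940 as deposited and 0.411 or more under the other settings. Its odor effect was 0.53 log2 both with this floor and as deposited, so the floor did not change the estimate. The call therefore came from the spread, the variance prior or the adjustment, and which of these was not tested. The common floor was the second tried. The first, at each array's own background, gave 10167 genes for the enrichment with octanoic acid (8174 higher, 1993 lower) and 2470 with clean air. The arrays differ in background, which such a floor turns into differences for every gene under it. The background was higher on the GFP+ than on the GFP- array in every odor pool, as in odor pool 2 (6.21 against 5.93 log2). Vehicle pools 1, 2 and 3 had the same order, and vehicle pool 4 the reverse (6.44 against 6.77). Whether this offset also raised dim genes in the enrichments as deposited was not tested. The common floor gave 1961 and 2088 genes with clean air and octanoic acid, and since genes at the floor on every array have no spread, the last floor tried kept only the 12495 genes above it on 4 arrays or more: 2650 and 2789 genes, and 0 for the odor effect. The first floor also reversed Micall2 (0.23) and Ctnna3 (0.33) in the odor effect and Esp16 (-0.31) and Vmn1r209 (-0.23) in GFP- cells, all under the background.

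Centring arrays on their medians gave 7653 genes with clean air and 9506 with octanoic acid, 2708 and 2935 of them among those called as deposited. The remaining settings stayed within 1.5 times the counts of 3006 and 3347, with 2133 to 3202 and 2287 to 3351 when each pool was left out. The class I median of -0.32 in the odor effect ran from -0.42 to -0.22 without single pools, and was -0.22 with the common floor (camera adjusted p 0.0574, against 1.13e-11 to 0.00816 under its other settings). With receptor-centred arrays it was -0.07 and with the first floor -0.14. In GFP- cells 0.20 was 0.07 and 0.09 under these 2 and ran from 0.13 (vehicle pool 4 out) to 0.40 (vehicle pool 1 out), and without odor replicate 1 the value of 0.13 no longer passed (adjusted p 0.155, against 1.70e-14 to 0.0220). The cause was not tested.

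Of the camera calls, the 1 list for the odor effect became 0 with an estimated correlation and 3 with receptor-centred arrays. The 14 with clean air became 4 and the 12 with octanoic acid 3 with an estimated correlation. The 1 in GFP+ cells became 0 and 2, and the 3 in GFP- cells 0 and 5, in the order given for the odor effect. The cause was not tested. fry, which compares a list with no change and not with other genes, called 0 lists in each of these 3 comparisons. With 1 of the 8 pools left out, the camera calls held in 8 of 8 cases for class I receptors in the odor effect and for all lists in the enrichments but class II receptors with clean air (5) and apoptosis genes with octanoic acid (7). With an estimated correlation class I receptors passed in 0. In the enrichments immediate early genes then passed in 8 cases with clean air and 7 with octanoic acid. Progenitor genes passed in 3 and 2, leukocyte genes in 4 and 2, and microvillous genes in 3 and 0. In the odor effect camera also called lists that had not passed: all olfactory receptors, vomeronasal receptors and sustentacular genes in 3 cases each, class II receptors in 2, and cell cycle and microvillous genes in 1 each, all 0 with an estimated correlation. Of 1136 values of single named genes under these settings 1132 kept their direction and side of the threshold and 4 reversed, as above; 8 had no value, being at a floor on every array. The planned test of class I receptors among those that rose with odor was not run, since 0 rose. Signal over background limits what can be seen: 127 of the rises and 280 of the falls with clean air lay at the background in both sorted samples.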

Other observations

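The use of unadjusted counts in the splits of the samples was chosen after 0 genes had passed, correlations within treatments after the pooled ones were seen, and the receptor families given as examples after their values were seen; the other tests were fixed before. Receptors of the same family tended to share their GFP enrichment. Of the 10 members of family 253 measured 9 rose with clean air, and all 7 members of family 179 did so (median 2.40 log2 with clean air and 1.60 with octanoic acid). Family 246 had medians of 2.67 and 2.60, family 225 had -3.30 and -3.55, and 10 of 18 members of family 135 fell with clean air. Over 917 receptors in 120 families of 3 members or more, family accounted for 26.9% of the variance with clean air and 27.3% with octanoic acid. Much of this share arises with shuffled families too: the median of 10000 permutations was 12.9% in each treatment. The highest of them gave 20.7% and 20.0% (permutation p = 0.0001, the smallest they can give). Shared ligands may underlie this, and so may related probes that bind each other's transcripts, which was not tested.

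Immediate early genes, lower in GFP+ cells, were weighed against the cells of the GFP- samples. If leukocyte RNA carried them, the list's mean should follow leukocyte markers across the 8 GFP- arrays: Pearson's r was 0.573 (exact permutation p = 0.139; adjusted over 2 tests, 0.203) and Spearman's rho 0.619 (exact p = 0.115), with r = 0.758 without the 2 arrays farthest from the median. For immature neuron and progenitor markers r was -0.509 (exact permutation p = 0.203) and rho -0.643 (exact p = 0.0962), with r = -0.419 without the 2 farthest. With each array set against the mean of its treatment r was 0.585 (exact permutation p = 0.214) and -0.509 (exact p = 0.436); within a single treatment 4 arrays are too few for a correlation, though for leukocytes the treatments looked unlike. With 8 arrays, these sources and a difference within neurons cannot be told apart.

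Other splits of the samples tested chance; since every split matches a count of 0, unadjusted counts were compared where no gene had passed. For the odor effect 14 of 35 splits of the pools gave as many genes at an unadjusted p under 0.05 as the real 871 (highest other 2654), for GFP+ cells 17 of 35 (real 716, highest other 2483) and for GFP- cells 23 of 35 (real 741, highest other 2258), so chance cannot be excluded. Among splits that part all numbered pairs the highest were 1445, 1275 and 1319. The highest splits held several times the real counts, which may point to a structure of the samples; this was not tested. For the enrichments, without the pool block, 1 of 35 splits, the real one, gave as many genes past the threshold. It gave 3025 with clean air and 2300 with octanoic acid, where the highest other split gave 0 in each. A share of 1 in 35 is the smallest these splits can give, and only 8 of them part all pairs. The other splits mix GFP+ with GFP- arrays on each side, which widens their spread and leaves few calls. The splits therefore cannot exclude chance by themselves.

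The first principal component of the arrays held 66.5% of the variance and parted GFP+ from GFP- samples; the second held 9.50%, with the GFP+ array of odor pool 3 at 76.5.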
